A study of Mus musculus with 6 samples.

How the data were processed

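Aortas of wild-type and knockout mice given Ang II were profiled by poly(A) RNA sequencing, with paired-end reads on an Illumina instrument per the labels' protocols. The series holds 6 libraries in 2 groups of 3, and the group of each library was taken from the genotype and treatment labels. The design text speaks of separate mice, but the labels give no animal identifiers, so p-values measure the spread between these libraries. The sources used here name the allele only as KO. The tissue label is aorta, while the protocol for the RNA speaks of an adipose type.

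A single table of 33919 genes was used. Its count columns hold whole-number gene counts, which the authors deposited without normalization. Its other value columns are FPKM per the file headers, a unit that divides fragments by gene length and library total, and how the authors computed it is not given in the sources used here. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and the mouse build mm8, without saying what each was used for. The program that counted reads and the strand setting are not given in the sources used here. The gene coordinates in the deposited table matched GENCODE release 21 on GRCm38 exactly for 91.2% of the shared genes, so positions are given as GRCm38 and not as mm8. The table had 0 rows without a gene name, and 0 columns of other samples were left aside.

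Low counts fell on multiples of 4 more often than chance: between 33.0% and 34.9% of values from 1 to 40, against 25%. A single read pair thus appears often to have added 4 to a count, and the nominal totals overstate the number of independent fragments. The floor for a gene with no count in a group was therefore set at 3 read pairs, or 12 deposited counts, per library. Fold changes against such a group are given as bounds from this floor, which covers counting error only. Total counts ran from 62.3 M to 71.5 M per library, of which 17.3 M to 23.4 M lay outside mitochondrial genes and their nuclear copies.

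Counts were tested with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and the quasi-likelihood F-test was applied to genotype alone, two-sided, with Benjamini-Hochberg adjustment over 16620 genes and a threshold of 0.05. The test planned for a table of FPKM alone was limma on log2(FPKM + 1), and since the table also held counts it was run as an alternative, as had been set out. CPM values are TMM-scaled. Before the data were examined, 46 gene lists were fixed for the aorta, Ang II, TGF-beta and other cell types a dissected aorta can hold, together with the alternatives and the rule for naming genes. Lists with at least 5 tested members, 43 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, then with an estimated correlation and with fry. GO and KEGG terms given in the table, with 15 to 300 tested genes, were tested the same way. For each list, adjustment over the list alone used the same gene p-values.

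Genes were named by the fixed rule: Otud1; 24 genes of the pathway and vessel wall; up to 12 genes per direction with the largest fitted change among those past the threshold, with a mean FPKM of at least 2 in 1 group and no overlap between groups, leaving out predicted genes and immunoglobulin segments; and from each list up to 4 members with the smallest p, or 2 where the list did not pass. Some genes this rule picks are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

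Scripts were tested on simulated counts drawn for 16620 genes from the observed means and library sizes, with 200 genes of mean CPM above 1 changed. At 1.5-fold 31% of the changed genes were recovered and at 2-fold 68%, with 4 false calls. In a second simulation a list of 30 genes moved by 1.5-fold was called and 0 of 40 random lists were. Genes were drawn independently of each other there, so this does not measure false calls among lists of correlated genes. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, robust empirical Bayes, a replicate block, leaving out each library in turn, a fold threshold, and limma on FPKM with pseudocounts of 0.1, 0.5 and 1, other filters and other scalings. Counts divided by 4, the removal of mitochondrial genes, and a mean CPM of at least 1 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.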

Results

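RNA sequencing was deposited for 6 libraries labelled as mouse aorta, 3 from wild-type mice and 3 from knockout mice, all given angiotensin II (Ang II), a peptide hormone that raises blood pressure and drives remodelling of the vessel wall. The series title names OTUD1, a deubiquitinating enzyme, and SMAD3, a transcription factor of the TGF-beta pathway, so the comparison asked how gene expression in the Ang II-treated aorta differed between the genotypes. The design text speaks of 3 mice in each group. Total counts were 70.5 M, 66.1 M and 62.3 M in the libraries labelled WT and 65.3 M, 70.6 M and 71.5 M in those labelled KO (M, megacounts). The 37 genes of the mitochondrial genome took 56.6%, 57.8% and 55.7% of the counts in the libraries labelled WT and 50.5%, 52.2% and 53.3% in those labelled KO. A further 14.3% to 16% lay in 7 annotated copies of mitochondrial sequence on chromosome 1 (24611535 to 24616197, GRCm38). The remaining genes therefore rested on 19.4 M, 17.3 M and 18.0 M counts in the libraries labelled WT and on 23.0 M, 23.4 M and 23.0 M in those labelled KO.

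Otud1 was higher in the libraries labelled KO. The gene (ENSMUSG00000043415, chromosome 2, 19657752 to 19660583, plus strand, GRCm38) had 593, 699 and 615 counts in the libraries labelled WT and 1033, 1141 and 1223 in those labelled KO. Its deposited FPKM was 3.05 ± 0.363 (SD, n = 3) in the first group and 5.26 ± 0.220 (SD, n = 3) in the second. The log2 fold change was 0.63 (SE 0.12, 1.55-fold higher in the libraries labelled KO), with an adjusted p of 0.0039 by edgeR's quasi-likelihood test. This direction goes against the genotype label, and the part of Otud1 removed in the knockout is not given in the sources used here. The groups are therefore named by their labels throughout, and each direction below is that of the libraries labelled KO relative to the libraries labelled WT.

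The most abundant nuclear transcripts in both groups were those of skeletal muscle fibres. Tnnc2, which encodes the troponin C of fast fibres and is named here for its abundance after its values were seen, had the highest FPKM, at 4322 ± 153 in the libraries labelled WT and 4823 ± 271 in those labelled KO (SD, n = 3 each). Acta1, which encodes skeletal muscle actin, came next, at 2358 ± 101 and 4241 ± 196. Of the 20 most abundant nuclear genes, 7 belonged to the fixed skeletal muscle list. By comparison, Acta2, the smooth muscle actin of the aortic media, reached 205.7 ± 4.26 CPM (counts scaled to a common library size) in the libraries labelled WT, against 4214 ± 53.5 CPM for Acta1 in the same libraries.

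Libraries grouped by label. The first principal component held 43.4% of the variance and separated the groups, and the second held 15.2% and set the third library labelled WT (-64) apart from the other 2 (37.3 and 28.1). Pearson correlations of log2 CPM across genes, which are not independent replicates, lay between 0.944 and 0.954 within a group and between 0.914 and 0.919 across groups.

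In the libraries labelled KO, genes of smooth muscle, collagen matrix and fibroblasts were lower, and genes of fatty acid synthesis and neutrophils were higher. Acta2 was 4.20-fold lower, falling from 205.7 ± 4.26 to 49.0 ± 0.990 CPM (SD, n = 3 each). Col1a1, a chain of type I collagen, was 4.28-fold lower. Fasn, the fatty acid synthase, was 3.94-fold higher, rising from 178.9 ± 7.15 to 704.3 ± 19.8 CPM, and Myh4, the myosin heavy chain of the fastest fibres, was 2.69-fold higher. Of 16620 genes tested, 3658 passed an adjusted p of 0.05, 1907 of them higher and 1751 lower, and at an unadjusted p of 0.05 the count was 5503. Changes of at least 2-fold were seen in 267 of the genes that were higher and 659 of those that were lower. The 3 values of one group all lay above the 3 of the other in 6421 genes, or 38.6%, against 10% by chance. The balance of directions depended on the processing. With another test, unit, filter and scaling, limma on the deposited FPKM tested 8308 genes and called 2708 higher and 736 lower. The median gene moved by 0.15 on the log2 scale there against -0.02 here. Scaling alone moved this balance. In limma on FPKM the share of higher genes among those called was 78.6% as deposited. It was 59.2% with median-ratio scaling and 51.6% with quantile normalization.

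**Figure D1:**
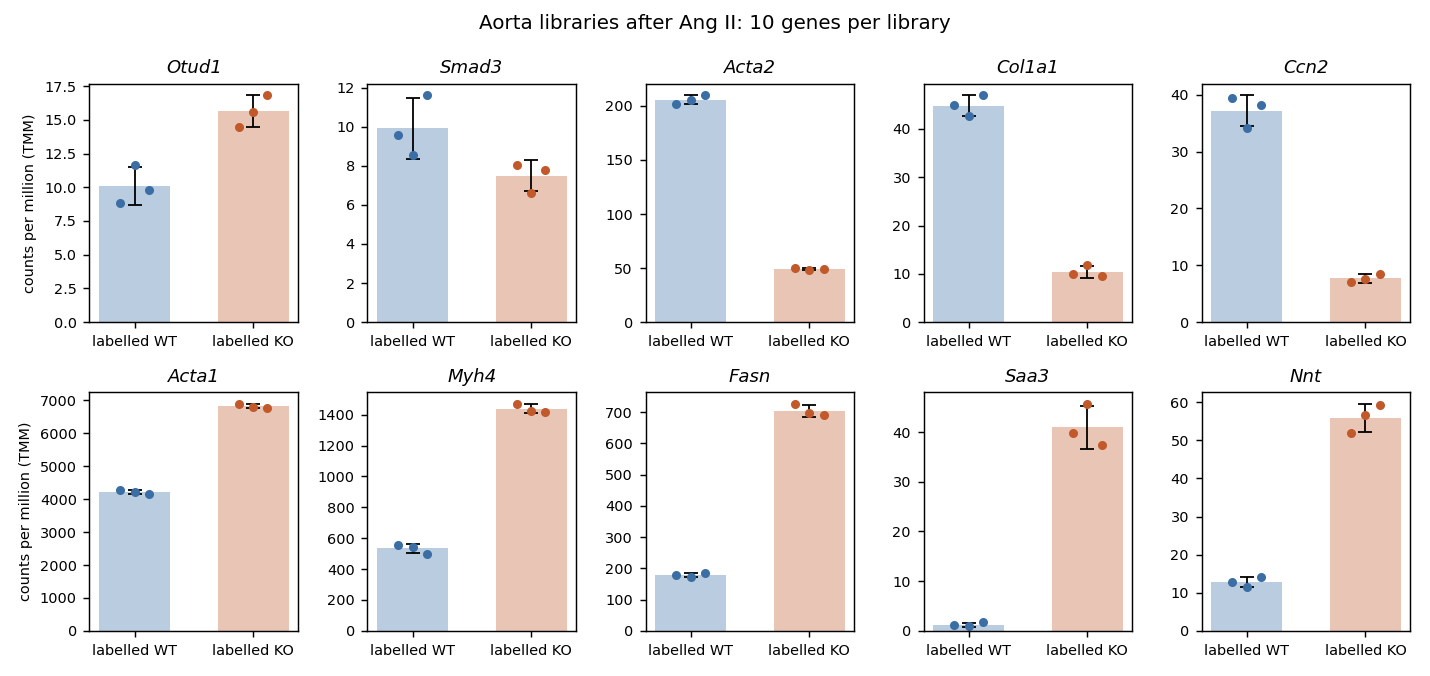
CPM (vertical axes, from 0, scaled by the trimmed mean of M values) of 10 genes in the 3 libraries labelled WT and the 3 labelled KO. Points are libraries, bars are group means and error bars are the SD; Otud1 and Acta1 lie higher in every library labelled KO, and Acta2, Col1a1 and Ccn2 lower.

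Among 20 genes of the smooth muscle contractile list, 15 were lower, 4 were higher and 1 did not pass the test, and adjusted over the list alone the counts were also 15 and 4. The median log2 change was -1.42, or -1.39 with Myocd, which is named after its values were seen and had no count in the libraries labelled KO, at its bound. Tagln fell by 1.92 and Myh11, the smooth muscle myosin heavy chain, fell by 1.68 on the log2 scale. The 4 members that were higher were Des (log2 change 1.23) and, chosen for naming after their values were seen, Tpm1 (0.26), Tpm2 (0.19) and Synpo2 (0.31), and Des, Tpm1 and Tpm2 are also expressed in skeletal muscle. The list passed the camera test (adjusted p = 2.9e-07, and 0.025 with an estimated correlation). Of 20 skeletal muscle markers, 13 were higher and 4 lower, also 13 and 4 adjusted over the list alone, with a median of 0.24. Myh4 (1.43), Myh2 (1.04), Acta1 (0.70) and Myot (1.11) rose on the log2 scale. The 4 that fell, named after their values were seen, were Tnnt1 (-0.77), Tnni1 (-0.94) and Myh7 (-0.33), which are genes of slow fibres, and Pvalb (-0.78), a calcium-binding protein of fast fibres. The list passed the test with the preset correlation (adjusted p = 5.1e-06) and not with an estimated one (adjusted p = 0.16 with an estimated correlation).

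Extracellular matrix genes were lower as a group. Of 39 tested genes of fibrillar collagens and matrix, 32 were lower and 1 higher, and adjusted over the list alone 33 were lower and 2 higher, with a median log2 change of -1.11. Col1a2 fell by 2.18, the small proteoglycans Dcn and Bgn by 1.69 and 1.11, Col3a1 by 0.97, Fn1 (fibronectin) by 0.71 and Postn (periostin) by 1.30. The list had the lowest camera p of the 43 lists tested (adjusted p = 2.7e-19, and 0.018 with an estimated correlation). Of 20 fibroblast and adventitial markers, 16 were lower and 1 higher, 18 and 2 adjusted over the list alone, among them Dpt (-1.38), Gsn (-0.82) and Mfap4 (-2.07). Matrix proteases and their inhibitors had 14 of 28 members lower and 2 higher, 15 and 2 adjusted over the list alone, with Adamts8 at -3.10, Timp2 at -1.18 and Mmp3 at -2.27. In the basement membrane list 8 of 16 members were lower and 1 higher, 8 and 2 adjusted over the list alone, with Col18a1 at -1.43 and Nid1 at -0.72, and the list's call did not hold with an estimated correlation (adjusted p = 0.096 with an estimated correlation). Smooth muscle markers fell in the same libraries, where 13 of 20 skeletal muscle markers were higher and 4 lower (adjusted p = 0.16 with an estimated correlation), and in a tendon and cartilage list chosen after seeing the data, which holds Comp and Fmod, 12 of 14 members were lower (median -3.91).

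Genes that respond to TGF-beta and SMAD3 were lower. Of 30 response genes 19 were lower and 0 higher, 20 and 0 adjusted over the list alone, with a median of -0.76 (camera adjusted p = 1.2e-10, and 0.018 with an estimated correlation). Ccn2, a connective tissue growth factor, fell from 37.2 ± 2.75 to 7.71 ± 0.752 CPM (SD, n = 3 each), 4.83-fold lower. Comp, which is also in the tendon and cartilage list, fell by 3.75 on the log2 scale. Nox4, an NADPH oxidase, fell by 1.51 (adjusted p = 0.00019). Smad3 had 9.90 ± 1.57 CPM in the libraries labelled WT and 7.48 ± 0.789 in those labelled KO (log2 change -0.41, adjusted p = 0.076, and 0.042 adjusted over the list alone). Smad2 was close to it (-0.40, adjusted p = 0.086, 0.046 adjusted over the list alone, and 0.022 without the third library labelled KO). Smad4 (-0.08), Smad7 (-0.12), Tgfbr1 (-0.12) and Tgfbr2 (-0.64) passed at neither level, with adjusted p between 0.27 and 0.72 over all genes, and Smad4, Smad7 and Tgfbr1 changed sign on the deposited FPKM scale in some settings. Tgfbr2 had 18.8, 4.46 and 15.2 CPM in the libraries labelled KO. Its change was -0.235 without the second of these and -1.03 without the first. In the list of TGF-beta and SMAD components 10 of 30 members were lower and 0 higher, 13 and 2 adjusted over the list alone, led by Tgfb3 (-1.71), Ltbp1 (-1.12) and Inhba (-3.79, and -4.46 without the second library labelled KO). Its call did not hold with an estimated correlation (adjusted p = 0.058 with an estimated correlation), although that estimate, -0.005, lay below the preset 0.01. The ligands Tgfb1 (-0.69, adjusted p = 0.012) and Tgfb2 (-0.91, adjusted p = 0.023) were also lower, but the call for Tgfb1 was lost without the first library labelled WT (adjusted p = 0.061), and that for Tgfb2 without the first or second library of either group (adjusted p = 0.053, 0.091, 0.062 and 0.076). Of the 20 mesenchymal transition genes 11 were lower and 1 higher, 14 and 1 adjusted over the list alone. Cnn1 fell by 2.71, and Fgfr1 rose by 0.88. Vim (-0.12) had an adjusted p of 0.075, 0.027 adjusted over the list alone and 0.026 without the third library labelled WT. Its sign changed on the deposited FPKM scale in some settings (0.029 at a pseudocount of 1). Snai1 (-0.31, adjusted p = 0.85) and Snai2 (-0.42, adjusted p = 0.36) passed at neither level. YAP/TEAD targets had 8 of 17 members lower and 0 higher, 9 and 0 adjusted over the list alone, with Wwtr1 at -0.56 and Ankrd1 at -1.98. The smooth muscle list shares Acta2, Cnn1 and Tagln with the mesenchymal transition list and 1 gene with the response list, and it fell in the same libraries, as did the fibroblast list. The median of the response genes (-0.76) lay no lower than those of the smooth muscle (-1.42) and fibroblast (-0.81) lists. Their fall is thus not set apart from that of these cell types.

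Endothelial markers did not move one way. Of 24 markers 5 were higher and 5 lower, 6 and 6 adjusted over the list alone, with a median of 0.05 (camera adjusted p = 0.95). Vwf rose by 1.27 and Egfl7 fell by 0.54. Pecam1 rose by 0.23 (adjusted p = 0.017), a call that was lost without the second library labelled WT (adjusted p = 0.068) and without replicate 2 or 3 labelled KO (adjusted p = 0.081 and 0.058), and Cdh5 had a log2 change of 0.08 (adjusted p = 0.35). In the angiotensin and endothelin list 2 of 15 members were higher and 2 lower, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.95). Ace, the angiotensin-converting enzyme, rose by 0.88 and Rgs5 fell by 0.33, while Agtr1a, the main Ang II receptor gene, had 1.70 ± 0.969 CPM in the libraries labelled WT and 1.91 ± 0.405 in those labelled KO (adjusted p = 0.85). None of the 28 cell cycle genes passed edgeR's quasi-likelihood test, over all genes or adjusted over the list alone; 3 had an unadjusted p below 0.05, DESeq2 called 1 and limma on FPKM 0. The 2 with the smallest p were Top2a (-1.63, adjusted p = 0.12) and Mcm6 (-0.42, adjusted p = 0.13, and 0.037 without the third library labelled WT).

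Immune and blood cell genes moved in both directions, in libraries where smooth muscle and fibroblast markers fell and 13 of 20 skeletal muscle markers were higher and 4 lower (adjusted p = 0.16 with an estimated correlation). Of the 16 genes of MHC class II and antigen presentation 11 were lower and 0 higher, 13 and 0 adjusted over the list alone, with Cd74 at -1.60, H2-Eb1 at -2.17 and H2-Aa at -1.73. Interferon-stimulated genes had 12 of 31 members lower and 1 higher, 15 and 1 adjusted over the list alone, with Irf7 at -1.18 and Bst2 at -0.87. Of 24 macrophage and monocyte markers 10 were lower and 1 higher, 11 and 1 adjusted over the list alone, with Plac8 at -2.29 and Lyz2 at -0.79. Complement and coagulation genes had 12 of 20 members lower and 1 higher, the same adjusted over the list alone, with C7 at -1.90. Many such proteins are made by hepatocytes, and in a list of hepatocyte secreted proteins chosen after seeing the data 16 of 19 members were lower (median -2.74). Haemoglobin transcripts, from red cells, were lower as well. Of 9 erythroid and platelet markers 5 were lower and 0 higher, the same adjusted over the list alone, and Hbb-bs fell from 211.2 ± 2.48 to 75.4 ± 5.45 CPM (SD, n = 3 each). The alpha-globin genes Hba-a1 (-1.22) and Hba-a2 (-1.78) share nearly all of their sequence, so the split of reads between them is uncertain. Neutrophil markers rose: 6 of 8 were higher and 0 lower, the same adjusted over the list alone, with a median of 3.46, or 3.18 with Retnlg at its bound, and 2.83 without the third library labelled WT. S100a9 went from 1.48 ± 0.327 to 11.2 ± 0.867 CPM and Csf3r from 0.659 ± 0.244 to 5.07 ± 0.765 CPM. In the B and plasma cell list 2 of 16 markers were lower and 0 higher, the same adjusted over the list alone, with Ighm at -1.58, and the call did not hold with an estimated correlation (adjusted p = 0.11 with an estimated correlation).

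Genes of fatty acid synthesis and of oxidative phosphorylation were mostly higher. Of 15 lipogenesis genes 12 were higher and 1 lower, 12 and 2 adjusted over the list alone, with a median of 0.71 (camera adjusted p = 2.3e-11, and 0.018 with an estimated correlation). Acaca and Acacb, the acetyl-CoA carboxylases, were 3.25-fold and 2.01-fold higher, and Acly was 2.71-fold higher. Of 49 nuclear genes of oxidative phosphorylation 38 were higher and 2 lower, 42 and 4 adjusted over the list alone, with a smaller median of 0.29; Atp5b rose by 0.46 and Cox4i1 by 0.36. The 13 mitochondrially encoded transcripts had 7 members lower and 0 higher, 8 and 0 adjusted over the list alone, with mt-Co1 at -0.40. That call did not hold with an estimated correlation (adjusted p = 0.41 with an estimated correlation), nor with fry (adjusted p = 0.090), and under quantile normalization of the FPKM values the median was 0.006. In the hypoxia list 9 of 21 members were higher and 4 lower, 11 and 4 adjusted over the list alone, and the 4 members with the smallest p, Eno1 (1.55), Ldha (0.72), Hk2 (1.06) and Pgk1 (0.57), all encode glycolytic enzymes. The hypoxia call did not hold with an estimated correlation (adjusted p = 0.11 with an estimated correlation). Fatty acid oxidation had 7 of 20 members higher and 0 lower, 9 and 2 adjusted over the list alone, with Acadvl at 0.44 (adjusted p = 0.096 with an estimated correlation). Glucocorticoid response genes had 7 of 14 members higher and 2 lower, 9 and 2 adjusted over the list alone, among them the metallothioneins Mt1 (2.82-fold higher) and Mt2 (2.50-fold higher). Of 20 adipocyte markers shared by white and brown fat 9 were higher and 6 lower, 9 and 7 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.42). Ucp1, the uncoupling protein of brown fat, reached 231.8 ± 3.95 CPM in the libraries labelled WT and 388.5 ± 21.3 in those labelled KO, while the other 13 tested brown adipocyte markers included falls such as Dio2 (-1.30). That list had 7 of 14 members higher and 2 lower, 8 and 2 adjusted over the list alone, and did not pass camera (adjusted p = 0.10), whereas fry gave an adjusted p of 0.010. The extraction protocol speaks of an adipose type although the tissue label is aorta, so the share of fat in these libraries is uncertain. In the same libraries 13 of 20 skeletal muscle markers were higher and 4 lower (adjusted p = 0.16 with an estimated correlation).

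**Figure D2:**
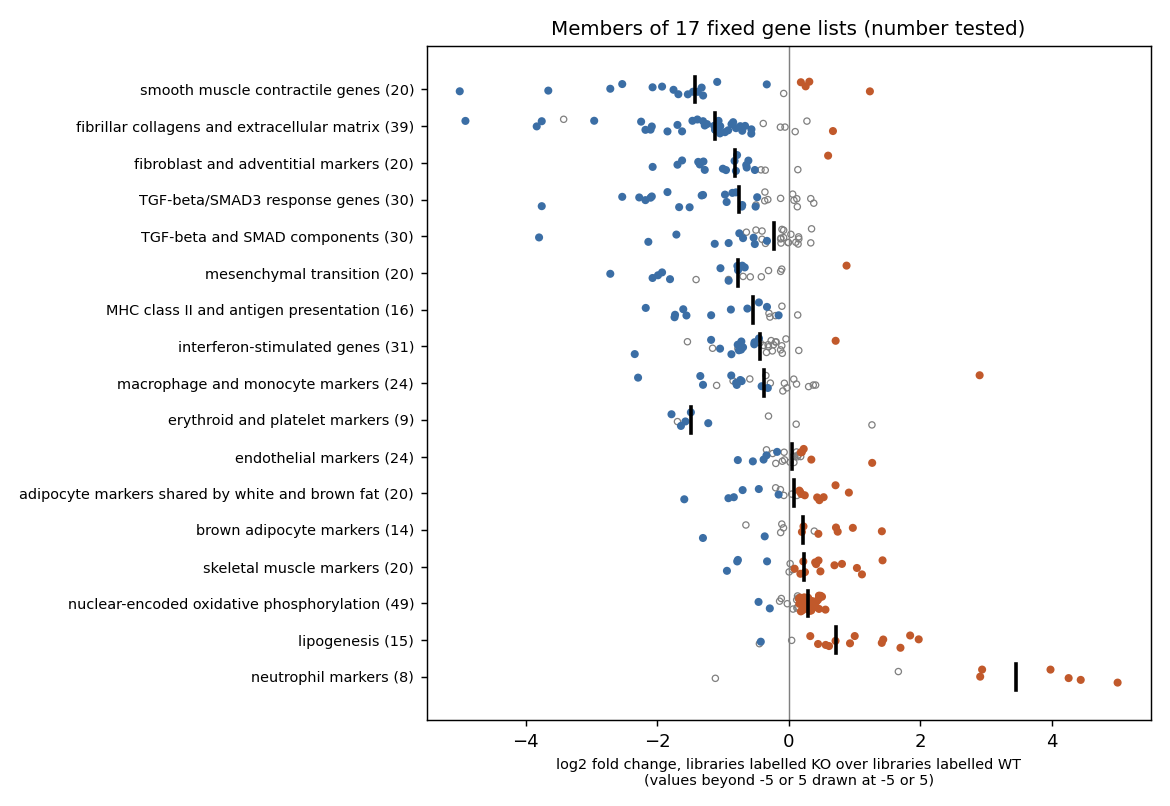
Log2 fold change (horizontal axis, libraries labelled KO over libraries labelled WT) of the tested members of 17 gene lists. Points are genes, filled where the adjusted p was below 0.05, and black bars are list medians, from -1.49 for erythroid and platelet markers to 3.46 for neutrophil markers, with points beyond 5 in either direction drawn at 5; fitted values of genes with no count in one group are no bounds, and the mitochondrially encoded list, which changed sign with scaling, is not drawn.

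Immediate early genes, which respond to tissue handling, had 15 of 26 members lower and 2 higher, 20 and 4 adjusted over the list alone, with Jund at -1.33, Klf4 at -0.90 and Egr1 at -1.39 (camera adjusted p = 2.4e-06, and 0.026 with an estimated correlation). Of 14 mesothelial and epithelial markers 5 were lower and 0 higher, the same adjusted over the list alone. Epcam and Cdh1 had no count in any library labelled KO and were at least 9.23-fold and 8.63-fold lower there. That list's call did not hold with an estimated correlation (adjusted p = 0.18 with an estimated correlation). In a list of intestinal and squamous epithelium chosen after seeing the data, which shares Krt8 and Krt19 with it, 13 of 14 members were lower. Ossification and cartilage genes had 5 of 10 members lower and 0 higher, the same adjusted over the list alone, with Mgp, an inhibitor of vascular calcification, at -1.36 (adjusted p = 0.070 with an estimated correlation). Of 16 Schwann cell and neuron markers 2 were lower and 0 higher, the same adjusted over the list alone, with Mbp at -1.54 (adjusted p = 0.11 with an estimated correlation). BMP and Notch targets had 6 of 19 members lower and 2 higher, 7 and 2 adjusted over the list alone, with Id1 at -0.56 (adjusted p = 0.19 with an estimated correlation, and 0.064 at the preset one without the second library labelled KO). In all, 28 of 43 lists passed camera with a preset correlation, 7 higher and 21 lower, and 17 with an estimated correlation. The 11 lists that lost their call did not all have correlations above the preset 0.01. Estimates were lower for TGF-beta components (-0.005), B and plasma cells (-0.012), fatty acid oxidation (-0.034) and Schwann cells (0.007). A higher correlation therefore does not account for the loss in these lists. The others that lost their call had higher estimates, and whether these account for their loss was not tested. The fibroblast list kept its call, but its camera adjusted p went from 1.6e-11 to 0.018 although its estimate, -0.004, lay below 0.01. The estimated setting thus raised p-values also where the correlation was lower, and a call lost under it does not show that a list was unchanged. With fry, which asks whether the genes of a list move one way and does not compare them with other genes, 32 passed. Of 2606 annotation terms 334 passed, 107 higher and 227 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.227 and 412 had an unadjusted p below 0.05.

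Of the 12 genes named for the largest rises, all with a mean FPKM of at least 2 in 1 group and no overlap between groups, S100a8, S100a9 and Retnlg belong to the neutrophil list. Saa3, an acute-phase serum amyloid, rose 32.1-fold, from 1.28 ± 0.406 to 40.9 ± 4.28 CPM (SD, n = 3 each). Retnlg had no count in the libraries labelled WT and was at least 10.7-fold higher in those labelled KO. S100a8 (log2 change 3.98), Lcn2 (2.94), S100a9 (2.91), Itih4 (2.90), Apoc3 (2.69), Wfdc21 (2.43), Fam107a (2.23), Ctxn3 (2.19), Nnt (2.12) and Gnmt (2.05) followed. The change of S100a8 was 6.21 without the second library labelled WT and 3.38 without the first, that of Apoc3 was 3.60 without the first library labelled WT, and the call for Wfdc21 was lost without the first library labelled KO (adjusted p = 0.081). Of the 12 named for the largest falls under the same rule, Krt8 and Krt19 belong to the epithelial list and Comp and Chad to that of ossification and cartilage. Lypd8 and Oit1 had no count in the libraries labelled KO and were at least 52.7-fold and 24.96-fold lower. Both belong, with Sprr2a1, Sprr2a2, Krt8 and Krt19, to the list of intestinal and squamous epithelium chosen after seeing the data. In that list 13 of 14 members were lower, 5 of them with no count in any library labelled KO. Among all genes called, 73 had no count in the libraries labelled KO and 18 had none in those labelled WT. Whether the libraries differed in their share of such tissue was not tested. Sprr2a2 (-7.34) and Sprr2a1 (-7.30), near-identical paralogs whose reads cannot be assigned with certainty, Chad (-5.59), Fmod (-4.91), Sfrp2 (-4.68), Krt8 (-4.52), Scgb1a1 (-4.45), Tnmd (-3.98), Comp (-3.75) and Krt19 (-3.51) followed. Leaving out 1 library labelled KO moved Sprr2a1 to -7.89 and Sfrp2 to -5.54 (the first library), Krt8 to -5.72 (the second) and Scgb1a1 to -5.99 (the third).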

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

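The counts divided by 4, the removal of mitochondrial genes and their nuclear copies, and the minimum mean CPM were chosen after seeing the data; the other settings were planned. All directions are those of the libraries labelled KO, in which Otud1 goes against the label. Of 125 genes tested and named here besides Otud1, 103 kept their direction and their side of the threshold under every setting in which they were tested. The same held for 18 of 43 lists. Filters left some genes untested in some settings, and limma on FPKM at a pseudocount of 1 tested 8308 genes. No gene called here was called in the opposite direction under any setting. Leaving out 1 library in turn gave between 2878 and 3171 genes, 27 to 29 lists and 296 to 334 terms. The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.21, 0.03 and 0.14 across genes. With a replicate block 3255 genes were called. Small changes can be missed, since 31% of simulated 1.5-fold changes were recovered. Only 200 of 16620 genes were changed in that simulation, so this is not the recovery rate of the real comparison.

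The cause of the following moves was not tested, except where fewer genes were tested, a fold threshold was added or only the scaling of FPKM was changed. A change of at least 2-fold left 926 genes, 267 higher and 659 lower. DESeq2 called 5233 genes, 2603 higher and 2630 lower. Without the low-count filter edgeR gave 531 terms. On FPKM, limma called 736 genes lower at a pseudocount of 1, 727 at 0.1, 729 at 0.5, 754 with no filter, 666 as TPM (2959 higher), 729 with robust empirical Bayes and 845 with array weights (2970 higher). The share of higher genes was 78.6% at a pseudocount of 1 against 52.1% on counts. On FPKM, median-ratio scaling gave 1834 higher and 1264 lower and quantile normalization 1514 and 1421, so the balance of directions moved with the scaling in the same test and unit. At a mean FPKM of at least 5, with 2698 genes tested, 1685 were called, 266 of them lower, with 10 lists and 89 terms. Estimated correlations left 17 lists and 0 terms, and quantile normalization 18 lists. Terms past the threshold on FPKM numbered 212 at a pseudocount of 1, 215 at 0.1, 213 at 0.5, 219 with median-ratio scaling, 209 as TPM, 203 with quantile normalization, 212 with robust empirical Bayes and 195 with array weights.

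Changes of sign among genes named here were nearly all in genes that had not passed the test. Log2 changes on FPKM at pseudocounts of 1, 0.1 and 0.5 and as TPM were 0.057, 0.072, 0.064 and 0.091 for Smad4, 0.014, 0.025, 0.019 and 0.037 for Tgfbr1, and 0.029, 0.030, 0.029 and 0.068 for Vim. With no filter and with robust empirical Bayes they were 0.057 for Smad4, 0.014 for Tgfbr1 and 0.029 for Vim, and with array weights 0.010 for Tgfbr1 and 0.0003 for Vim, which was at 0.029 with a mean FPKM of at least 5. Smad7 was at 0.010 with no filter and 0.031 as TPM. Quantile normalization put Cdh5 at -0.034 and mt-Co2, which had passed, at 0.0058. Tnnc2 (0.007 on counts as deposited) was at -0.0066 with counts divided by 4 and at -0.0171 with the minimum mean CPM, and ranged from -0.0093 to 0.0175 with 1 library left out. With 1 library left out, Smad4 ranged from -0.16 to 0.01, Snai1 from -1.36 to 0.13 and Agtr1a from -0.25 to 0.43.

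The test's direction turned for 7 lists, given with their medians. Endothelial markers were at 0.045 with fry, 0.048 without the edgeR filter, 0.16 on unfiltered FPKM and -0.014 to 0.051 with 1 library left out. Adipocyte markers were at 0.085 with fry, 0.27 at a mean FPKM of at least 5 and -0.057 with quantile normalization. The angiotensin list was at -0.16 without the edgeR filter, 0.007 on unfiltered FPKM, -0.042 with quantile normalization and -0.26 to -0.053 with 1 library left out. The reactive oxygen list was at 0.005 without the edgeR filter and -0.019 to 0.07 with 1 library left out; on FPKM it was at 0.20, 0.23 and 0.23 at pseudocounts of 1, 0.1 and 0.5, 0.10 unfiltered, 0.22 at a mean of at least 5, 0.085 with median-ratio scaling, 0.23 as TPM, 0.20 with robust empirical Bayes and 0.22 with array weights. Cardiac markers were at 0.68 with a mean FPKM of at least 5 and at -0.51 to -0.20 with 1 library left out. With quantile normalization fatty acid oxidation was at 0.031 and the mitochondrially encoded list at 0.006.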

Other observations

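The tests of explanations and the added lists in this part were chosen after the results were seen, while the lists fixed beforehand and the tests of lists and terms were planned, and every direction is that of the libraries labelled KO, in which Otud1 goes against the label. Gene lists chosen after seeing the data describe other parts of the difference and are no independent evidence of their direction. Of 14 fast-twitch fibre genes 10 were higher and 1 lower (median log2 change 0.44), while of 11 slow-twitch genes 3 were higher and 6 lower (median -0.33). Of 21 muscle stress and remodelling genes 17 were higher, among them the small heat shock protein Cryab (1.29). Acute-phase proteins had 10 of 13 members higher (median 1.5), whereas hepatocyte secreted proteins had 16 of 19 lower (median -2.74), with Alb (albumin) at -3.31. Tendon and cartilage genes had 12 of 14 members lower (median -3.91). Intestinal and squamous epithelium had 13 of 14 lower, with a median of -6.32, or -4.58 with the 5 members that had no count in one group at their bounds.

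Among annotation terms with a preset correlation, genes of the mitochondrial large ribosomal subunit (36 of 59 higher, 0 lower) and of the proteasome complex (37 of 60 higher, 6 lower) were higher, and neither term held with an estimated correlation (adjusted p = 0.227 with an estimated correlation for both). Nnt, the mitochondrial transhydrogenase, rose from 12.8 ± 1.36 to 55.9 ± 3.71 CPM (SD, n = 3 each), a log2 change of 2.12, above the range of -0.46 to 0.56 over the oxidative phosphorylation list. Some C57BL/6 substrains carry a deletion in this gene. Whether the groups differed in substrain was not tested, and such a difference could not be told apart from genotype in any gene here. Within 5 Mb of Otud1, 5 of 37 tested genes passed the test (13.5%, against 22.01% of all tested genes).

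Other lists fixed beforehand did not pass camera. The medians were 0.21 for brown adipocyte markers, -1.07 for mast cell markers, 0.11 for the circadian clock, -0.14 for the unfolded protein response, -0.43 for T and NK cell markers, -0.26 for cytokines and adhesion molecules, -0.05 for NF-kappaB response genes, 0.02 for reactive oxygen enzymes, -0.40 for cardiac muscle, -0.10 for lymphatic endothelium and -0.04 for the OTU family. Of these, fry passed the circadian clock (adjusted p = 0.00069), brown adipocyte (0.010), mast cell (0.013) and lymphatic (0.045) lists, and it also passed the cell cycle list (0.025). The mast cell list passed camera without the first library labelled WT (adjusted p = 0.035) and without the first labelled KO (0.028). Median and test direction differed in sign for endothelial, cardiac, lymphatic, angiotensin, reactive oxygen and OTU family lists, and the adipocyte list had a median of 0.09 and a mean of -0.05.

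Smooth muscle, fibroblast and matrix genes were lower, and 13 of 20 skeletal muscle markers higher, in the libraries labelled KO. The call for the skeletal muscle list was lost with an estimated correlation (adjusted p = 0.16 with an estimated correlation). A larger share of skeletal muscle as the only cause is argued against by the 4 skeletal muscle markers called lower, all 4 of them also lower without overlap in FPKM; muscle of another fibre composition stays open. A smaller share of vessel wall tissue may lower these wall genes alike, and the fibroblast median lay 0.61 above the smooth muscle median (95% bootstrap interval over genes -0.18 to 1.07), which leaves it open. The endothelial median lay 1.46 above the smooth muscle median (0.69 to 1.9), so endothelial markers did not fall with them; capillaries of muscle and fat also hold endothelium, and their share is not known here. A lower matrix programme in wall cells after loss of OTUD1 is the biological candidate, although the Otud1 transcript was not lower in the libraries labelled KO. Under it, matrix genes were set out to fall further than smooth muscle genes. The matrix median lay instead 0.304 above the smooth muscle median (-0.43 to 0.79). This prediction was not met, but the interval includes 0, so the test decides nothing. A smaller share of tendon as the only cause of the matrix gene fall may lower collagens too, and the matrix genes outside the tendon and cartilage list had a median of -1.06. This misses the value near 0 set out for tendon as the only cause, but tendon cells also make collagens outside that list, so it does not exclude it. The last 3 cannot be told apart, since each lowers matrix genes and these libraries hold the tissue as a whole.

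Otud1 was higher in the libraries labelled KO. Exchanged labels may explain it, but the lowest Otud1 count in the libraries labelled WT was 593, so neither group lacks the transcript. A larger share of skeletal muscle is another candidate explanation, and the log2 change of Otud1 lay 0.40 above the skeletal muscle median. Both stay open, because the removed part of the gene, and the cells in which it was removed, are not given in the sources used here. A transcript kept by the allele was not tested.

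Libraries of a group lay close together against the distance between groups, although the third library labelled WT stood apart on the second principal component. The ratio of variance to mean was 10.96, 10.97 and 13.2 in the libraries labelled WT for genes from a CPM of 4, 16 and 64 upwards, and 36.3 in the highest of these 4 bins; in the libraries labelled KO it was 10.2, 10.2, 13.04 and 41.8. Repeat libraries of one RNA pool could give a constant ratio. In the highest bin it was up to 4.09 times that in the lowest, in the libraries labelled KO. The median coefficient of variation (SD over mean) there was only 2.73% in the libraries labelled WT and 2.52% in those labelled KO. It was 6.74% and 5.99% from a CPM of 16 to 64, and higher still below that. Whether the libraries were repeats of a pool thus remains open. If they were, the p-values given here would not measure differences between mice. The smooth muscle list mean varied between libraries of a group by an SD of at most 0.058 on the log2 scale. This lies below the range assumed for 3 mice per group that differed little, and since that range was not measured it excludes nothing.

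With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3658 genes, 28 lists and 334 terms, and 1 of the 10 splits, the real one, reached each value. The highest of the other splits were 2 genes, 14 lists and 11 terms.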
